A study of Pardosa milvina with 12 samples.

How the data were processed

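Whole-body RNA of the wolf spider Pardosa milvina was sequenced from 12 libraries in 4 groups of 3: adult females exposed to predator cues during development, unexposed adult females, offspring of exposed spiders and offspring of unexposed spiders, the offspring at the 3rd instar. RNA was extracted with a Maxwell RSC simplyRNA kit and libraries were made with the NEBNext Ultra II Directional kit, per the labels' protocols. The protocols speak of 3 exposed and 3 unexposed adults. They do not say whether an offspring library holds 1 animal or several, or which mother it came from, so p-values for the offspring measure only the spread between these samples. The sex of the offspring is not labelled.

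The deposited table holds 400642 clusters of assembled transcripts, each with a cluster ID and best-hit descriptions from protein and nucleotide databases, and 1 column of values per library. These deposited values are expected counts, meaning estimated read counts that need not be whole, and between 86.6% and 98.0% of the values of a library were whole to 2 decimals. CASAVA 1.6, RSEM 1.2.28 and DESeq2 1.26.0 are named in the submitters' processing notes. The assembler, the annotation searches and any filter are not given in the sources used here, nor is whether the counting used the strand. No genome was used, so clusters have no coordinates and are identified by cluster ID, product description and the species of the protein best hit. The best hit names the closest database entry and not the animal that the RNA came from. Near-identical clusters of 1 product can share reads, so values of single clusters of multigene families such as haemocyanins, spidroins and toxins are uncertain.

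Totals ran from 3416720 to 29064091 counts. A share of a library's counts has a 95% Wilson interval of at most ±0.0528 percentage points, and a share of the counts on clusters with a spider best hit one of at most ±0.0701. A count of 0 allows 3 counts, which is 0.103 to 0.878 CPM across libraries. Intervals and floors cover counting error only, since the reads carried no molecular identifiers. Folds against a group with 0 counts in all 3 libraries are given as lower bounds, with 3 counts over the whole group as the floor and, above it, the smaller of the mean CPM and the CPM of the pooled counts of the other group.

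Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, R 4.3.3), after scaling by TMM and removal of low clusters by filterByExpr with its default minimum of 10 counts. P-values were adjusted by Benjamini-Hochberg over all clusters tested, with 0.05 as the threshold. Adults and offspring were fitted separately for the effect of exposure, the unexposed adults and unexposed offspring for stage, and all 12 libraries together for the difference between the 2 exposure effects. Levels are CPM on TMM-scaled totals, as mean ± SD of 3 libraries. CPM of 1 cluster differ slightly between comparisons because each comparison has its own scaling.

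A total of 26 function lists, built from product descriptions, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were run beside it. Another 5 lists held clusters annotated to insects, bacteria, fungi with microsporidia and protists, nematodes and viruses. Because a list with few members can hold several clusters of 1 product, the tests were repeated with 1 entry per product. The correlation of the adult and offspring effects across clusters used differences of mean log2 CPM (prior count 2) and exact permutation of the exposure labels within each stage, 400 labelings in all.

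Named genes followed a rule fixed before the data were examined. It takes up to 12 products per direction among clusters past the threshold with no overlap of the groups, and, where fewer than 5 qualify, the 5 named products with the smallest p in that direction at a mean log2 CPM of at least 1. It adds up to 4 members of each list with the smallest p in each exposure comparison, and the 5 with the smallest p per direction for the difference of effects. The tests, lists and most alternatives were also fixed before the data were examined. Later additions were a fit on the 49819 clusters with a spider best hit, depth class as a covariate, clusters of 1 product summed, the offspring comparison without its 2 deepest libraries, and searches of the nucleotide descriptions for ribosomal RNA, human, cricket, springtail, mite and bacterial sources. List medians with bounds or RLE scaling, permutation tests of list shares and the use of confidence intervals or counting error in 3 tests of explanations were also added after the results were seen.

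The alternatives that were planned covered RLE scaling, DESeq2 1.42.0, limma voom with sample quality weights, no filter, at least 50 counts in at least 3 libraries, replicate number as a block, each library left out, only named products, removal of clusters annotated to other organisms, all 12 libraries in 1 fit and a test against a 1.5-fold change. The numbers of calls depended strongly on the tool, the filter and the libraries included, and the planned edgeR test is reported as the result whatever the alternatives gave. RLE in place of TMM moved the median log2 fold change of all tested clusters from −0.62 to −0.49 in adults, from 0.02 to −0.29 in offspring and from −0.05 to −0.54 between stages.

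The tests were checked on simulated counts drawn from the means and library sizes of each comparison, with 200 clusters changed. At a dispersion of 0.1 the adult test recovered 82.1% of 4-fold, 95.5% of 16-fold and 93.9% of 64-fold changes among 23280 clusters, and the offspring test 82.1%, 91.0% and 97.0% among 32724. The test of the difference of effects recovered 29.9%, 95.5% and 97.0% among 43836, and the stage test 88.1%, 98.5% and 97.0% among 30972. At the spread estimated from the data, 0% of changes of 4-, 16- or 64-fold were recovered in any of the 4 comparisons. In those runs 17488, 23293, 37196 and 18758 simulated clusters passed the filter for adults, offspring, the difference and stage. The data had 24330, 35604, 55031 and 32624. Changed clusters that failed the filter counted as not recovered. The simulated spread may thus exceed that of the libraries, so the 0% holds for the simulation and does not set the smallest change these tests could find. A proteasome list shifted 4-fold was called at the preset correlation in all 3 list comparisons, while at the estimated correlation and spread its adjusted p by camera was 0.0264 in adults, 0.128 in offspring and 0.427 between stages. Simulated clusters were drawn independently of each other, so these runs do not check the preset correlation of 0.01. In the data the estimated correlation of the proteasome list was 0.198 in adults, 0.35 in offspring and 0.329 between stages.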

Results

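Pardosa milvina is a small ground-living wolf spider. The series asked how gene expression in the whole body differs between spiders that met chemical cues of predators throughout development and spiders that did not, and whether the offspring of the 2 kinds of mother differ. It holds 12 libraries: 3 exposed adult females, 3 unexposed adult females, 3 libraries of offspring of exposed spiders and 3 of offspring of unexposed spiders, called here adult exposed, adult control, offspring of exposed and offspring of control.

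Depth differed 8.5-fold between libraries. Adult control 1 (29064091 counts), offspring of control 3 (28171041) and offspring of exposed 2 (26903318) lay far above the other 9. Adult exposed libraries 1 to 3 held 6437872, 3416720 and 4204159 counts, and adult control 2 and 3 held 6757267 and 7333101. Every adult exposed library was thus shallower than every adult control library, so depth and exposure went together in adults. The two-sided exact permutation p for this was 0.1, the smallest possible. Offspring of exposed 1 and 3 held 4588042 and 8466569 counts, and offspring of control 1 and 2 held 4899888 and 7114487. Of the 400642 clusters, 213461 (53.3%) exceeded 5 counts in exactly 1 library and 4473 (1.12%) did so in all 12.

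RNA other than spider messenger RNA took a large and uneven part of the libraries. Clusters with a spider protein best hit held 59.9% of the counts of adult control 1 and 12.9% of those of offspring of control 1. Ribosomal RNA held between 7.84% (adult control 1) and 46.1% (adult control 2). Clusters whose nucleotide best hit was human held 24.6% of offspring of control 1 and 10.2% of adult exposed 3, and at most 4.92% in the other 10. Mesostigmatid mites, a group with many predators and parasites of small arthropods, held 25.4% of adult control 2 and at most 0.624% elsewhere. Crickets, a usual prey of captive spiders, held 4.65% of offspring of exposed 2 and 3.89% of offspring of control 2. Springtails held 4.13% of adult exposed 1. By a two-sided exact permutation test, which cannot give a p below 0.1 for 3 against 3 libraries and so cannot show that shares did not differ, the p between exposed and control was 1.0 for the human share, 0.8 for mites and 0.6 for springtails in adults, and 0.5, 0.6 and 0.3 in offspring. The cricket share was 0.806% ± 0.097 in adult exposed and 0.162% ± 0.195 in adult control libraries (SD, n = 3), without overlap of the groups, with an exact permutation p of 0.1, the smallest possible, against 0.9 in offspring. Of the 5 lists by annotated organism, nematodes held the most, with 4.67% ± 1.28 of counts in adult exposed, 7.95% ± 7.64 in adult control, 5.63% ± 5.56 in offspring of exposed and 4.49% ± 1.92 in offspring of control. Bacteria held 1.92%, 4.96%, 0.97% and 1.62% in the same order, fungi with microsporidia and protists 1.65%, 1.0%, 0.323% and 3.28%, insects 2.31%, 1.21%, 0.983% and 1.14%, and viruses 0.103%, 0.087%, 0.083% and 0.22%. The exact permutation p of these 5 lists lay between 0.4 and 0.9 in adults and between 0.1 (viruses) and 1.0 in offspring. By nucleotide best hit, Burkholderiales held 8.29% in adult exposed, 5.02% in adult control, 3.89% in offspring of exposed and 5.25% in offspring of control. The bacteria list thus missed bacterial clusters. The highest nematode shares, 16.75% in adult control 2 and 12.05% in offspring of exposed 3, came with the most ribosomal RNA (46.1% and 41.0%). Adult control 3 had 3.06% beside 37.6%. Such best hits do not show nematode RNA.

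**Figure D1:**
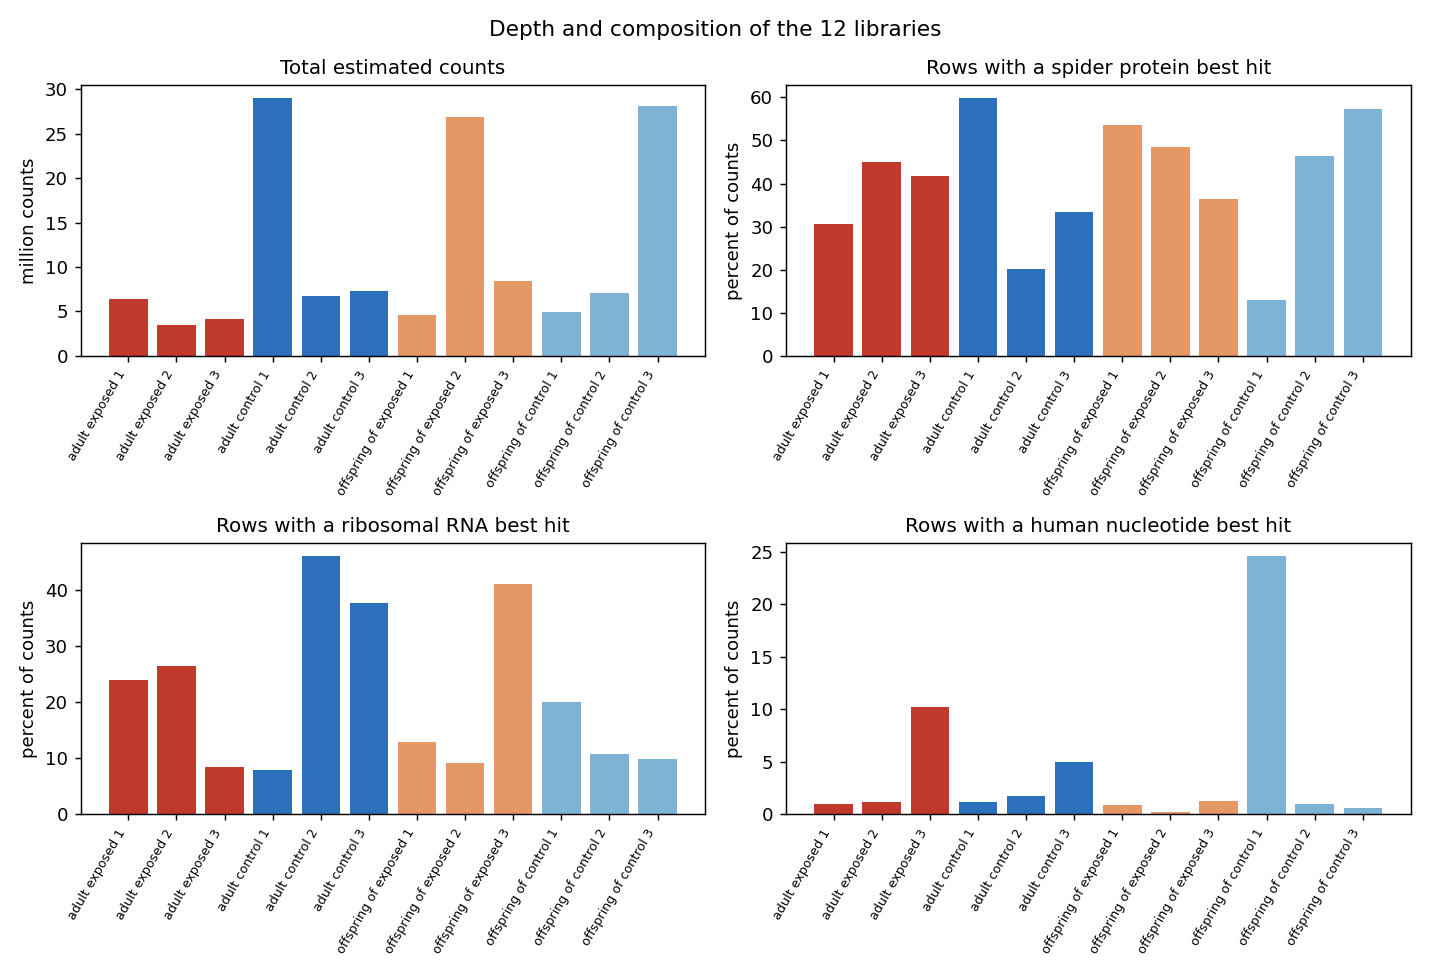
Bars give, for each of the 12 libraries, the total of expected counts and the percent of counts on clusters with a spider protein best hit, a ribosomal RNA best hit or a human nucleotide best hit, coloured by group. Adult control 1, offspring of exposed 2 and offspring of control 3 stand at 26903318 to 29064091 counts, and offspring of control 1 has 24.6% of its counts on human best hits.

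Libraries did not group by stage or exposure as a whole, apart from the adult exposed libraries. Over clusters with a spider best hit and no ribosomal RNA, the spread of log2 ratios between 2 libraries (a robust SD) had a median of 1.243 within groups and 1.389 across groups. The smallest values joined adult control 1 with offspring of control 3 (0.629, of which counting error alone gives 0.208) and offspring of exposed 2 with offspring of control 2 (0.805, counting error 0.219), while the smallest value within any group was 0.916. The closest library was of the same group for 3 of the 12, which were the 3 adult exposed libraries. With counts thinned to the lowest total this held for adult exposed 3 and offspring of exposed 1 alone. The first principal component took 35.6% of the variance and parted adult control 1, offspring of exposed 1, offspring of exposed 2, offspring of control 2 and offspring of control 3 from the other 7. The 3 deepest libraries all lay on the side of adult control 1. The components were not taken on thinned counts, so depth was not told apart from this division. Transcripts of the nervous system went with that division. The synapse list held 0.522% of spider counts in adult control 1, 0.456% in offspring of exposed 2, 0.526% in offspring of control 2 and 0.524% in offspring of control 3, and at most 0.313% in the other 8.

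**Figure D2:**
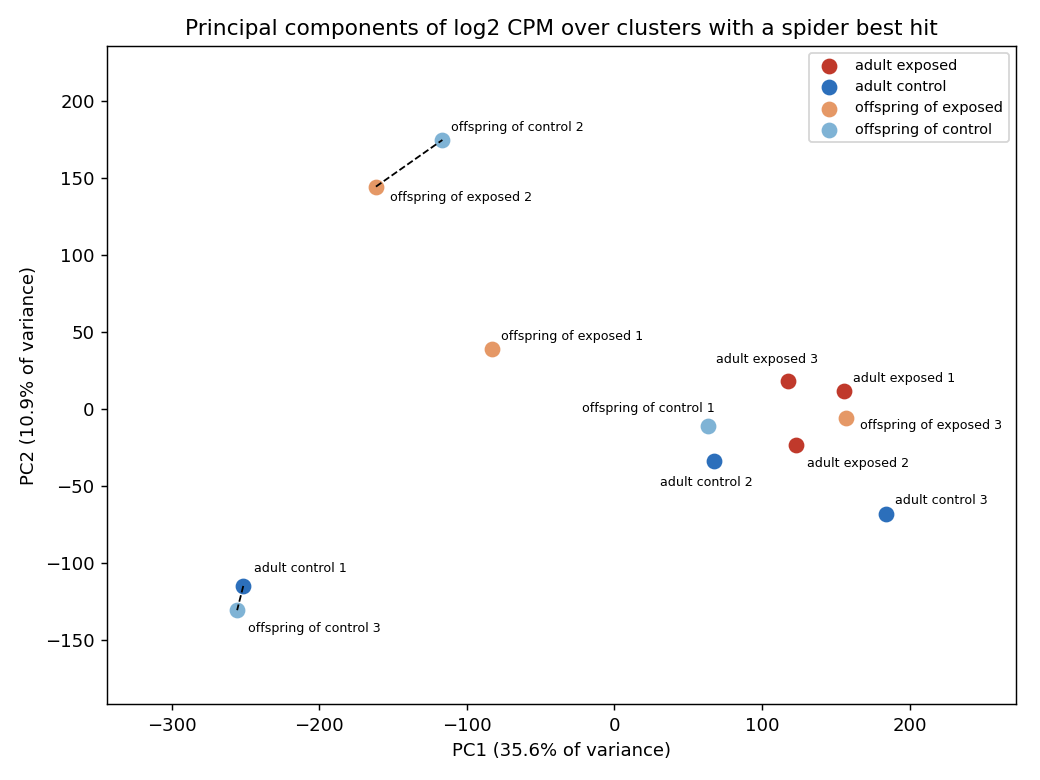
Each point is a library on the first 2 principal components of log2 CPM over clusters with a spider best hit, with the percent of variance on each axis and colours for the 4 groups. Dashed lines join the 2 pairs with the smallest spread, adult control 1 with offspring of control 3 (0.629) and offspring of exposed 2 with offspring of control 2 (0.805), both across groups.

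The first comparison asked which genes differ between adults that met predator cues and adults that did not. No single cluster passed the threshold. Silk genes as a group stood higher in exposed adults by a test that presets the correlation between genes, though not by one that estimates it. A set of 3 clusters of spidroin-2, a main protein of dragline silk, averaged 1805 ± 1736, 974 ± 938 and 940 ± 768 CPM in exposed adults and 92.4 ± 79.2, 25.4 ± 37.8 and 38.6 ± 27.7 CPM in controls (SD, n = 3), with log2 fold changes of 4.29, 5.26 and 4.61. By the first of these tests venom and digestive genes stood above the other genes, and chemosensory and visual receptors, haemocyanin and muscle below them, while by the other each had an adjusted p of 0.886. The downward direction of the receptors turned without adult control 1 (0.748) and that of haemocyanin without adult control 2 (0.901) or adult exposed 3 (0.439). Lateral-eye arrestin, which shuts off the light response of photoreceptors, was at 0.579, 0 and 0 CPM in exposed adults and at 10440, 933 and 108 CPM in controls. The smallest adjusted p of any receptor cluster was 0.233 by edgeR's quasi-likelihood test. The receptors' share of spider counts overlapped between the groups, at 0.891%, 0.51% and 4.377% in exposed adults and 8.465%, 4.652% and 0.637% in controls.

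By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 24330 clusters differed between exposed and control adults, and the smallest adjusted p was 0.0986. At an unadjusted p below 0.05 there were 828 clusters, where chance alone gives about 1216. DESeq2, run over 241463 clusters with its own filter, called 391, of which 356 were higher in exposed adults, and edgeR without a filter called 259. Limma voom on the same 24330 clusters called 0. In 7.2% of clusters the 2 groups did not overlap, against 10% by chance. The biological coefficient of variation was 1.51, so a typical cluster varied between libraries of a group by more than its mean. Leaving out adult control 3 gave 522 calls, adult exposed 2 117, adult exposed 3 68, adult control 2 63 and adult exposed 1 52, while leaving out adult control 1 gave 0.

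The named clusters with the smallest p were mostly present in 1 group and at 0 in the other. ATP-dependent RNA helicase DDX3Y (Cluster-217197.52013), a database name whose protein best hit here is the house spider Parasteatoda tepidariorum, had 0 counts in all exposed adults and 261 ± 249 CPM in controls, at least 1310-fold lower. Cactin (Cluster-217197.51569), a splicing-associated protein, was at least 402-fold lower and calnexin (Cluster-118550.4), a chaperone of the endoplasmic reticulum, at least 183-fold lower, at 38.5 ± 7.76 CPM in controls. In the other direction calmodulin (Cluster-217197.36889), a calcium sensor, stood at 93.3 ± 87.4 CPM in exposed adults and at 0 in controls, at least 733-fold higher; its protein best hit is the nematode Trichinella. Multiple coagulation factor deficiency protein 2 homolog, a cargo receptor of secretion, was at least 868-fold higher, VIP36-like protein, a lectin of the same pathway, at least 576-fold, and 1 cluster of troponin T, a regulator of muscle contraction, at least 318-fold. Their adjusted p ran from 0.0986 to 0.34 in edgeR's quasi-likelihood test, so none of them passed.

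Camera at the preset correlation called 6 of the 26 lists in adults. With an estimated correlation it called 0, each of the 6 having an adjusted p of 0.886, and fry also called 0 (smallest adjusted p 0.426). The silk list was the strongest: 9 of its 11 clusters were higher in exposed adults, its median log2 fold change was 4.29 against −0.62 for all clusters, and its adjusted p by camera was 2.58e-07. Of these clusters 0 passed over all genes, and 4 rose when adjusted over the list alone. Each of the 6 libraries could be left out without loss of the silk call (highest adjusted p by camera 0.00745), and the same held for venom (0.0258). Major ampullate spidroin 1 precursor (Cluster-217197.46941), another dragline protein, had 7.84 ± 7.43 CPM in exposed adults and 0 in controls, at least 70.6-fold higher. The silk share of spider counts was 2.15%, 0.068% and 1.4% in the exposed libraries and 0.003%, 0.097% and 0.164% in the controls, so adult exposed 2 lay inside the range of the controls.

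The venom list (155 clusters) and the digestive enzyme list (137 clusters) had adjusted p of 7.79e-05 and 0.000315 by camera in adults, in the higher direction, with 0 clusters of either past the test. Their medians, −0.06 and −0.11, were below 0 while their means, 0.1 and 0.08, and the test were upward, the median of all clusters being −0.62. With RLE scaling the venom median was 0.01 and that of all clusters −0.49. Astacin-like metalloprotease toxin 1 (Cluster-232769.2), a venom protease that both lists hold, had 21.8 ± 11.5 CPM in exposed adults and 0 in controls, at least 196-fold higher. U19-ctenitoxin-Pn1a, a peptide toxin, had 69.6 ± 28.7 CPM against 0.925 ± 1.602. Alpha-amylase 1, which digests starch and glycogen, went the other way at 0.813 ± 1.41 CPM against 74.2 ± 56.3. The digestive call was lost without adult control 1 (adjusted p by camera 0.506) and without adult control 2 (0.157), and with 1 entry per product (0.066).

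The lists of chemosensory and visual receptors (26 clusters, median −2.26), haemocyanin (56 clusters, −1.5) and muscle (141 clusters, −1.19) had adjusted p of 0.00562, 0.000951 and 0.00383 by camera in adults, in the lower direction. Adjusted over the list alone, 1 cluster fell in the first, arrestin, and 1 rose in the third, troponin T. Each of these 3 calls depended on more than 1 library, and leaving out any 1 of those ended it. Myosin heavy chain (Cluster-217197.33349), the motor of muscle, was at 4848 CPM in adult control 1, 407 and 74.5 CPM in the other controls and 61.2 ± 17.0 CPM in exposed adults. Transient receptor potential-gamma protein (Cluster-217197.16745), a channel of photoreceptors, was at 1432, 200 and 21.0 CPM in the controls and 47.4 ± 16.6 in exposed adults. Without adult control 1 the adjusted p by camera was 0.748 for muscle and 0.748 for the receptors, whose direction turned upward. The receptors' call was also lost without adult exposed 1 (0.0532), adult exposed 2 (0.444) or adult control 2 (0.148), and that of muscle without adult exposed 3 (0.146). Haemocyanin, the oxygen carrier of spider blood, took 9.19% of the spider counts of adult control 2, the library with the mite RNA. Without that library its adjusted p was 0.901, and without adult exposed 3 0.439, both in the upward direction.

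Other lists in adults did not pass. Neurotransmitter receptors and synthesis (adjusted p by camera 0.0588), glycolysis and gluconeogenesis (0.0788) and synapse (0.266) had medians of −1.82, −1.37 and −1.64. Synaptotagmin 1 (Cluster-217197.31712), a calcium sensor of neurotransmitter release, was at 910 CPM in adult control 1, 67.0 and 4.78 in the other controls and 6.70 ± 7.60 CPM in exposed adults. Glycogen phosphorylase, which releases glucose from glycogen, was at 1067, 35.4 and 43.2 CPM in the controls and 1.53 ± 2.65 in exposed adults. Perilipin-2, a coat protein of lipid droplets, was at 477 ± 347 CPM in exposed adults and 72.8 ± 10.4 in controls, and vitellogenin-6, a yolk precursor, at 642 ± 376 and 124 ± 142. The egg yolk list itself had an adjusted p of 0.266 by camera, and the remaining 16 lists had adjusted p between 0.0788 (transposable elements) and 0.95 (antioxidant enzymes). In immune defence 1 cluster rose adjusted over the list alone, the multiple coagulation factor deficiency protein 2 homolog.

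The second comparison asked whether the offspring of exposed spiders differ from those of unexposed spiders. There 10 of 35604 clusters rose and 0 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 of them with a named product. Polyadenylate-binding protein 1 (Cluster-217197.39004), which binds the tails of messenger RNA, rose from 0.145 ± 0.251 CPM in offspring of control to 216 ± 169 CPM in offspring of exposed (SD, n = 3), a log2 fold change of 10.13 ± 2.31 (SE), at 114, 123 and 411 CPM in the 3 exposed libraries. Heme-binding protein 2 (Cluster-10336.4) rose by a log2 fold change of 9.21 ± 1.97 (SE), but was at 2337 CPM in offspring of exposed 1 and at 3.45 and 0.964 CPM in the other 2. Stress response protein nst1 (8.67 ± 1.76) and protein TAR1 (10.53 ± 2.17), a name given to reading frames on the antisense strand of ribosomal RNA genes, were both highest in offspring of exposed 3, at 11230 and 1354 CPM. Their protein best hits are a nematode and a malaria parasite, and the nucleotide best hit of this TAR1 cluster (Cluster-217197.37632) is spider 28S ribosomal RNA. With RLE scaling the adjusted p of these 4 clusters by edgeR's quasi-likelihood test lay between 0.0867 and 0.174.

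Leaving out single libraries ended most of these calls. For polyadenylate-binding protein 1 the adjusted p by edgeR's quasi-likelihood test was 0.0947 without offspring of control 3, 0.242 without offspring of exposed 2 and 1.0 without any of the other 4 libraries. For the heme-binding protein it was 0.0947 without offspring of control 3 and 1.0 without offspring of exposed 1, offspring of control 1 or offspring of control 2, and its log2 fold change without offspring of exposed 1 was 0.78. For nst1 it was 0.18 without offspring of exposed 1, 0.0947 without offspring of control 3 and 1.0 without offspring of exposed 3, offspring of control 1 or offspring of control 2. For TAR1 it was 0.245 without offspring of exposed 1 and 1.0 without offspring of exposed 3, offspring of control 1 or offspring of control 2.

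The other 6 clusters have no named product. Of all 10, 9 had over 90% of the summed CPM of the offspring of exposed in 1 library, and the 2 groups overlapped in 3. The adjusted p of the 10 by edgeR's quasi-likelihood test ran from 0.00139 to 0.0416. At an unadjusted p below 0.05 there were 639 clusters, where chance gives about 1780, and 5.3% of clusters had no overlap of the groups against 10% by chance. DESeq2, run over 310755 clusters with its own filter, called 3553, of which 3508 were lower in offspring of exposed, while edgeR without a filter and limma voom on the same 35604 clusters each called 0. With RLE scaling 2 calls were left, and with only the 14110 clusters with a spider best hit 0. Leaving out offspring of exposed 1, offspring of control 1 or offspring of control 2 gave 0 calls. Leaving out offspring of control 3 gave 6, offspring of exposed 3 7 (5 of them among the 10) and offspring of exposed 2 11 (9 among the 10).

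Several named clusters came close. Soma ferritin, an iron store, was at 34.9, 3.74 and 1696 CPM in offspring of exposed and at 2.35 ± 3.37 in offspring of control, with an adjusted p of 0.0919 by edgeR's quasi-likelihood test. Guanine nucleotide-binding protein subunit beta-2-like 1 (Cluster-213866.1), the ribosomal scaffold RACK1, had 0 counts in all offspring of exposed and 88.9 ± 44.3 CPM in offspring of control, at least 921-fold lower, with an adjusted p of 0.0605. Another RACK1 cluster of the same assembly group (Cluster-213866.0) went the opposite way, as given in the third comparison. The fall of this cluster therefore does not show that RACK1 as a product was lower. Laminin subunit alpha-2 (Cluster-217197.16698), of the basement membrane, and the venom peptides U5-lycotoxin-Ls1a and U4-lycotoxin-Ls1a were at 1549, 1079 and 994 CPM in offspring of control 3 and below 5 CPM in the other 5 offspring libraries.

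**Figure D3:**
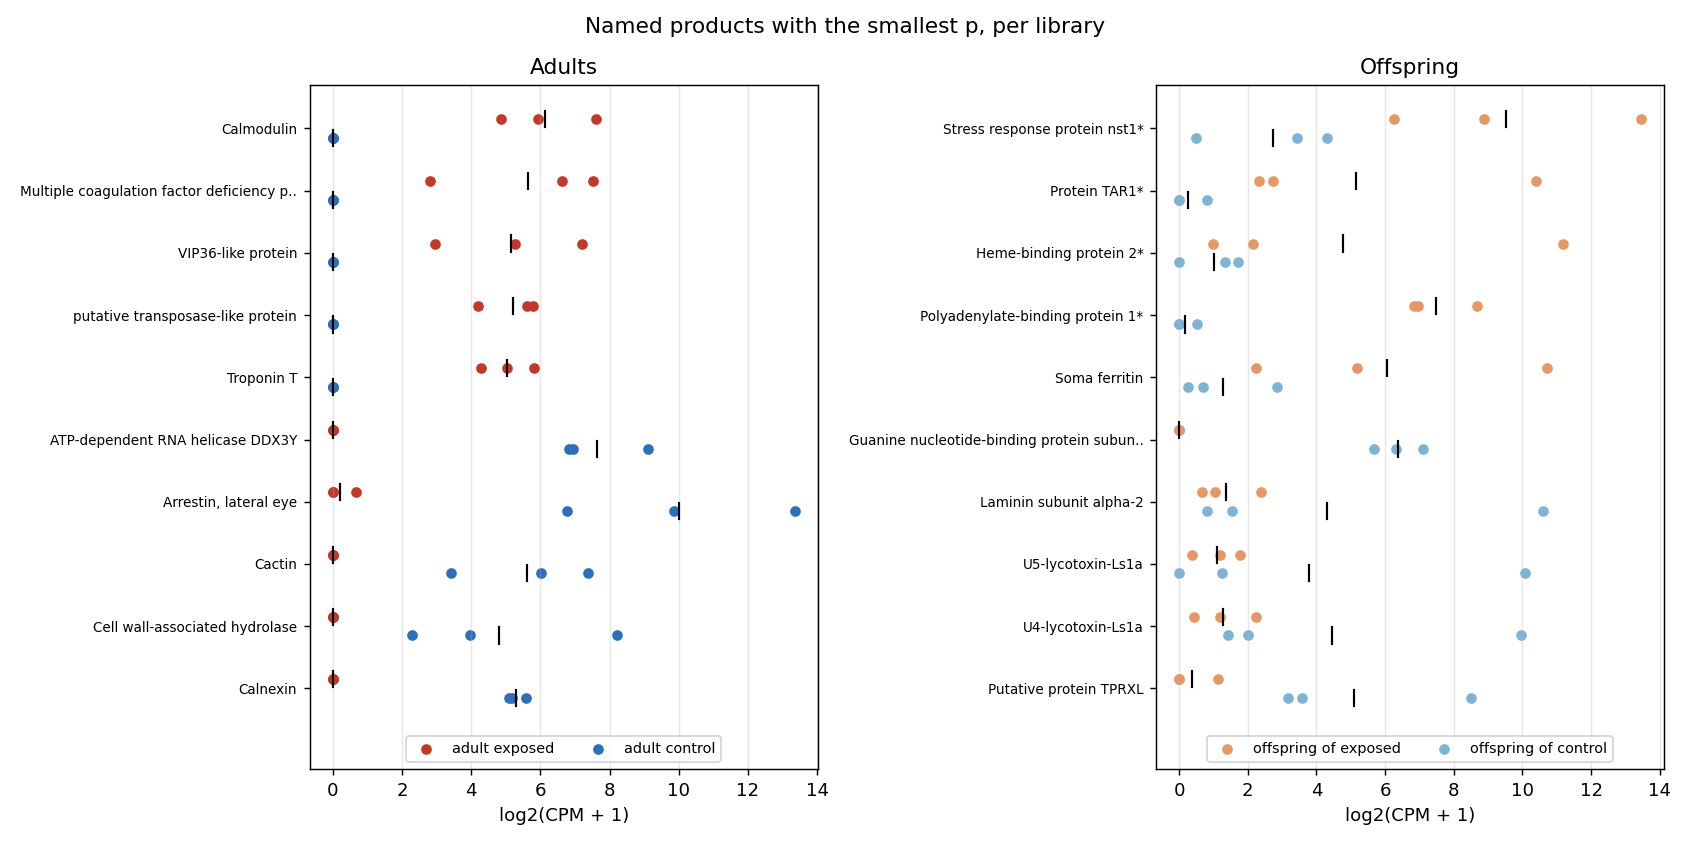
Points are single libraries on a log2(CPM + 1) axis for the 5 named products with the smallest p in each direction, adults on the left and offspring on the right, with a short line at the mean of each group of 3 and an asterisk for those past the threshold. The adult products are at or near 0 in 1 whole group, and the products past the threshold in offspring, except polyadenylate-binding protein 1, are carried by 1 library.

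Camera at the preset correlation called 10 of the 26 lists in offspring, 7 upward and 3 downward. The number was 7 without offspring of exposed 1, 6 without offspring of exposed 3, 15 without offspring of control 1 and 7 without offspring of control 2 or offspring of control 3. With an estimated correlation it called 0 (smallest adjusted p 0.977) and fry called 0 (smallest 0.67). The proteasome, which degrades tagged proteins, was the strongest: 59 of its 66 clusters were higher in offspring of exposed, with a median log2 fold change of 1.29 against 0.02 for all clusters and an adjusted p by camera of 3.84e-08. None of its clusters passed, neither over all genes nor adjusted over the list alone, by edgeR's quasi-likelihood test. Proteasome subunit alpha type-5 was at 78.1 ± 33.5 CPM against 11.2 ± 15.98, and 26S proteasome non-ATPase regulatory subunit 7 at 38.3 ± 15.9 against 5.07 ± 4.47. The list's share of spider counts was 0.761%, 0.35% and 0.397% in offspring of exposed and 0.179%, 0.297% and 0.255% in offspring of control, with an exact permutation p of 0.1, the smallest possible. The proteasome call held without each of the 6 libraries (highest adjusted p by camera 0.0004), as did that of the egg yolk and germline list (58 clusters, median 0.58, adjusted p 0.00214, highest without a library 0.0179). With 1 entry per product the proteasome call held (1.62e-07) and that of egg yolk was lost (0.0647), as it was over clusters with a spider best hit alone (0.0757).

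Cytosolic ribosomal proteins had 189 of 244 clusters higher in offspring of exposed (median 0.77, adjusted p by camera 0.00263). The 60S ribosomal protein L10 was at 198 ± 23.5 CPM against 15.7 ± 13.7. That call was lost without offspring of exposed 1 (0.391), offspring of exposed 3 (0.571), offspring of control 2 (0.993) or offspring of control 3 (0.22). Silk (9 clusters, median 1.16, adjusted p 0.00023) had 1 cluster that rose adjusted over the list alone, spidroin-1 at 139 ± 119 CPM against 1.52 ± 2.64, and was lost without offspring of control 3 (0.202). Digestive enzymes (134 clusters, median 0.94, adjusted p 0.000114) rested on offspring of exposed 3, where chymotrypsin-like protease CTRL-1 reached 1691 CPM and an astacin-like metalloendopeptidase 744 CPM, and were lost without it (0.426) and without offspring of control 3 (0.0626). Venom (107 clusters, median 1.19, adjusted p 0.00013) was called upward although 4 of its clusters fell when adjusted over the list alone, among them the lycotoxins carried by offspring of control 3. It was lost without offspring of exposed 3 (0.693) and offspring of control 2 (0.182).

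Haemocyanin (51 clusters, median 2.13, adjusted p by camera 0.0135) was high in offspring of exposed 1, at 4.29% of spider counts against 0.153% to 0.696% in the other 5 offspring libraries. Without that library the list was called in the other direction (0.0448), and over clusters with a spider best hit alone it was not called (0.425). The 3 lists in the lower direction were cuticle and chitin (72 clusters, median −0.38, adjusted p 9.92e-05), chemosensory and visual receptors (39 clusters, −1.3, 0.0126) and transposable elements (752 clusters, −0.36, 0.000335). A cuticle protein (Cluster-217197.31933, with a fruit fly best hit) was at 181, 5.63 and 4.15 CPM in offspring of control and 0.479 ± 0.829 in offspring of exposed, while endochitinase, an enzyme that cuts chitin, stood at 707, 6.51 and 0 CPM in offspring of exposed. Opsin Rh4, a visual pigment, was at 182 CPM in offspring of control 3 and between 2.71 and 20.9 CPM in the other 5. The cuticle call was lost without offspring of exposed 1 (0.6), offspring of exposed 3 (0.0538), offspring of control 2 (0.14) or offspring of control 3 (0.0626), that of the receptors without offspring of exposed 1 (0.0762) or offspring of control 3 (0.845), and that of transposable elements without offspring of control 1 (0.289). With 1 entry per product all 3 downward calls were lost, each with an adjusted p by camera of 0.168.

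With iron and haem handling, which includes the heme-binding protein, 1 of 85 clusters rose over all genes and 2 rose adjusted over the list alone, and the list had an adjusted p of 0.132 by camera. Transferrin, an iron carrier of the blood, was at 203 ± 126 CPM against 20.05 ± 29.2. Heat shock proteins (0.108), lipid metabolism (0.132), oxidative phosphorylation (0.413), neurotransmitter receptors (0.359), synapse (0.63), immune defence (0.282), muscle (0.928) and DNA methylation and chromatin (0.975) did not pass by camera in offspring. Nor did antioxidant enzymes (0.554), detoxification enzymes (0.678), sperm and axoneme (0.525), moulting hormones (0.602), glycolysis and gluconeogenesis (0.413), cell cycle and DNA replication (0.413) or insulin and growth signalling (0.928). In all 3 list comparisons the medians were the same to 2 decimals with clusters at 0 in a whole group set to their bound.

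**Figure D4:**
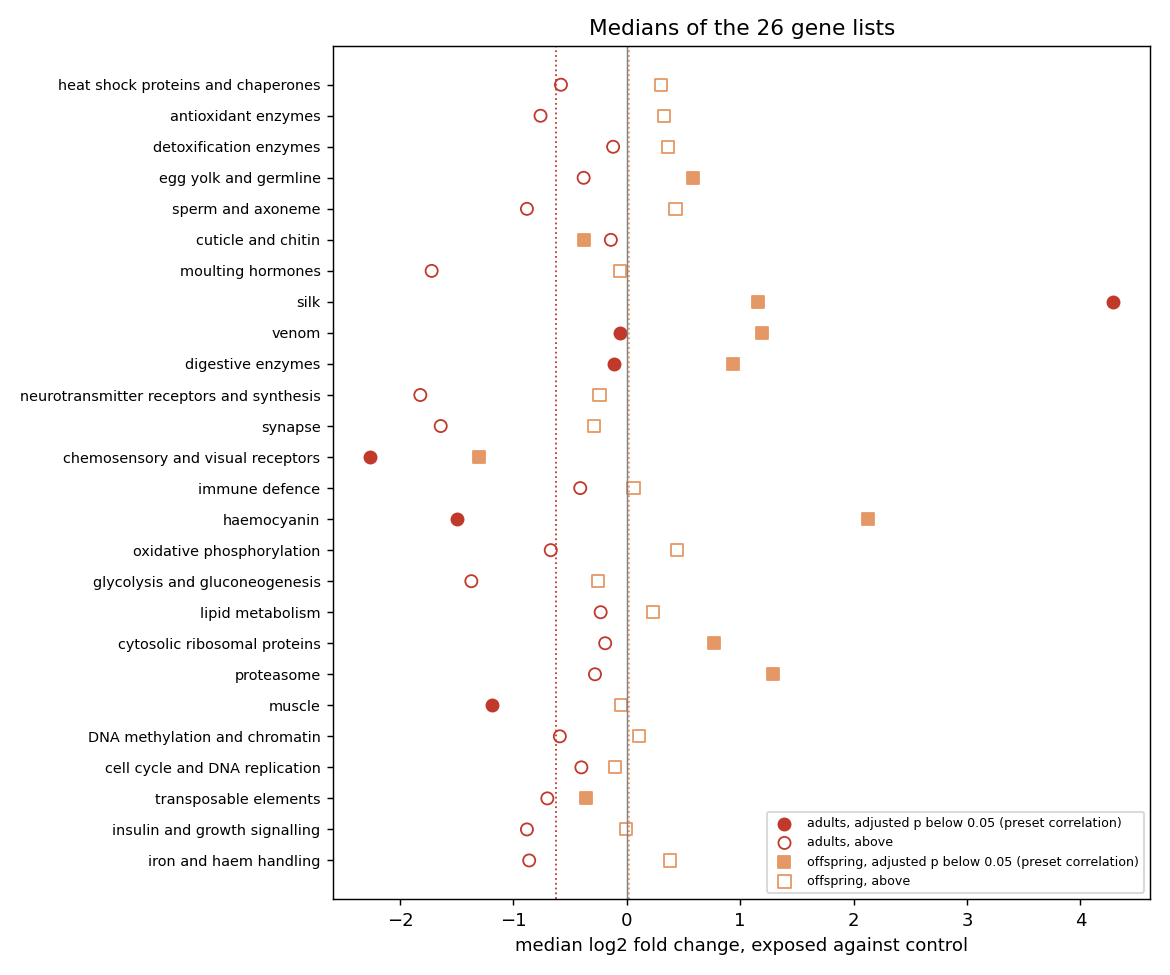
Each symbol is the median log2 fold change of a list, exposed against control, for adults (circles) and offspring (squares), filled where camera at the preset correlation gave an adjusted p below 0.05. Dotted lines mark the medians of all clusters, −0.62 in adults and 0.02 in offspring, and silk in adults stands at 4.29; none of the filled lists passed with an estimated correlation.

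The third comparison asked whether exposure acts differently on adults and on offspring. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 55031 clusters, the exposure effects differed in 80, more positive in adults in 14 and more negative in 66. The median log2 difference of all 55031 clusters was itself −1.25, and 0.98 without adult control 1. The larger number of negative calls was therefore not told apart from a shift of all clusters. DESeq2 ran over 391477 clusters, left 356827 of them without an adjusted p and called 1660, while limma voom called 3. At an unadjusted p below 0.05 there were 3579 clusters against about 2752 by chance. Tubuliform spidroin 1 (Cluster-10069.3), the silk protein of egg sacs, was at 0 in adult exposed and 59.5 ± 98.8 CPM in adult control, and at 117 ± 202 in offspring of exposed and 0 in offspring of control. Where it had counts its SD exceeded its mean, so 1 library can carry each of these means. A pair of RACK1 clusters of 1 assembly group went opposite ways: Cluster-213866.1 was at 276 ± 22.0, 100 ± 149, 0 and 84.0 ± 54.9 CPM in adult exposed, adult control, offspring of exposed and offspring of control, and Cluster-213866.0 at 0, 165 ± 143, 330 ± 173 and 68.6 ± 81.6. With at least 50 counts in 3 libraries, with named products only, or with clusters of a spider best hit only, edgeR called 0. Leaving out single libraries gave 3, 6 and 4 calls without adult exposed 1, 2 and 3, 52, 13 and 11 without adult control 1, 2 and 3, 8, 16 and 6 without offspring of exposed 1, 2 and 3, and 85, 3 and 45 without offspring of control 1, 2 and 3.

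Across the 55031 clusters the adult and offspring effects had a Pearson r of 0.195 and a Spearman rho of 0.184, with exact two-sided permutation p of 0.5 and 0.54 over 400 labelings. Genes are not independent replicates, and relabelled exposure gave an r of up to 0.499 in size. The 2 effects share no library. Leaving out 1 library gave an r of −0.051 without offspring of control 3, 0.023 without offspring of exposed 3 and 0.111 without adult control 1, and between 0.14 and 0.254 without each of the other 9.

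The fourth comparison set adult control against offspring of control, where stage and the unlabelled sex of the offspring cannot be separated. The 2 named clusters past the threshold were a lipid carrier and a yolk precursor, both higher in adults. Apolipophorins-like (Cluster-186183.0), a lipid carrier of the blood, was higher in adults by a log2 fold change of 11.10 ± 1.82 (SE), and vitellogenin-4 (Cluster-217662.0), a yolk precursor, by 10.89 ± 1.91, with adjusted p of 4.28e-05 and 0.000207 by edgeR's quasi-likelihood test. Both were carried by adult control 3, with 12840 and 6774 CPM, against 75.5 and 74.0 CPM in adult control 2 and 0.836 and 0.044 CPM in adult control 1. Without adult control 3 or offspring of control 1 the adjusted p of both was 1.0 by edgeR's quasi-likelihood test, and that of vitellogenin-4 was 0.0529 without adult control 2 and 0.057 without offspring of control 2. In all, 11 of 32624 clusters were higher in adults and 0 in offspring by that test, with 279 clusters at an unadjusted p below 0.05 where chance gives about 1631. The other tools called mostly clusters higher in offspring. DESeq2 ran over 243036 clusters and left 198195 of them without an adjusted p. It called 1556, with 235 higher in adults and 1321 in offspring. Limma voom called 15402, with 4138 higher in adults and 11264 in offspring. In edgeR's test, leaving out adult control 2 gave 1 call, offspring of control 2 7, adult control 1 66, adult control 3 26, offspring of control 1 89 and offspring of control 3 20.

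A cuticle protein (Cluster-217197.36205) was at 9.29 ± 14.1 CPM in adults and 501 ± 439 in offspring, and another (Cluster-217197.31933) at 0 in adults and 63.6 ± 103 in offspring, at least 229-fold higher, without passing the test. Camera at the preset correlation called 17 lists for stage. The highest medians in adults were haemocyanin (2.17, adjusted p 9.94e-12), digestive enzymes (1.56, 2.59e-07) and venom (1.12, 7.22e-12), beside −0.05 for all clusters. Called in the direction of offspring were cuticle and chitin (−0.05, 0.0058), silk (5 clusters, −1.92, 0.0421), synapse (−0.16, 0.0421) and DNA methylation and chromatin (−0.12, 0.038). With 1 entry per product the calls of cuticle (0.293), synapse (0.469) and chromatin (0.0868) were lost, as were antioxidant enzymes (0.0582) and egg yolk (0.0684), while haemocyanin and silk could not be run. The direction of silk turned without adult control 1 (0.235), offspring of control 1 (0.257) or offspring of control 2 (0.605), that of digestive enzymes without adult control 3 (0.899) and that of synapse without offspring of control 3 (0.612). With an estimated correlation 0 lists were called, the smallest adjusted p being 0.0819 for oxidative phosphorylation. The number was 4 without adult control 3, 5 without adult control 2, 10 without offspring of control 3 and 11 without offspring of control 2. With RLE scaling the median of all clusters was −0.54, and the medians of 7 of the 13 lists called higher in adults were below 0 (heat shock proteins, antioxidant enzymes, egg yolk, immune defence, oxidative phosphorylation, proteasome, and iron and haem handling), though above that of all clusters. The calls of egg yolk (0.0718), immune defence (0.0556) and proteasome (0.0556) were lost with it, which left 10 higher in adults, and so was that of silk (0.0589).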

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

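The tests of ribosomal RNA and of other organisms for the library pairs, of a mislabelled library, of calls carried by 1 library, of overlap among the offspring calls, of depth for clusters at 0 and of the others of the 37 clusters with a high own level were chosen after the result was seen; the other tests were chosen before. The rules that read 5 tests were changed after their values were seen: those on ribosomal RNA and other organisms for the library pairs (parted into 2) and for the offspring calls, on calls carried by 1 library, on depth for clusters at 0 (replaced by thinning) and on sibling clusters.

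The effects of exposure differed between adults and offspring in 80 clusters by edgeR's quasi-likelihood test of the difference itself, which is what brought them here. The log2 difference (adults minus offspring) was 17.13 for peroxidasin homolog (Cluster-233077.0), 14.15 and −15.92 for 2 clusters of guanine nucleotide-binding protein subunit beta-2-like 1 (Cluster-213866.1 and Cluster-213866.0), 12.78 for phosphoribosylaminoimidazole-succinocarboxamide synthase, 8.5 for laminin subunit alpha-2 (Cluster-217197.16698) and 13.03 for type IV pilus biogenesis and competence protein PilQ. It was −25.35 for tubuliform spidroin 1, −16.04 for vitellogenin-4-like (Cluster-119986.1), −21.39 for cell wall-associated hydrolase and −21.06 for a haemocyanin G chain (Cluster-217197.42673). In all of these but laminin and vitellogenin-4-like at least 1 group was at 0 in its 3 libraries, so the fitted values depend on the prior count and are no bounds. The 2 clusters of guanine nucleotide-binding protein subunit beta-2-like 1 share 1 assembly group and went opposite ways, so neither shows a difference for the product as a whole. The protein best hits of the synthase and of PilQ are an antelope, and that of the hydrolase a nematode. Of 50 drawn regroupings of exposure within stages, the real one included, 42 called at least 80 clusters, with 1562 as the highest and 138 as the median of the others. Chance is therefore not excluded for this count.

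The closest libraries came from different groups: adult control 1 with offspring of control 3, and offspring of exposed 2 with offspring of control 2. Depth alone is argued against, since with every library thinned to the lowest total 2 of the 2 pairs stayed each other's closest. Ribosomal RNA clusters were left out when the pairs reached spreads of 0.629 and 0.805, below the 0.916 of the closest pair within a group. The pattern was first seen that way, so this restates it and tests no link with ribosomal RNA content. That link stays open: ribosomal RNA held 7.84% and 9.82% in the first pair and 9.075% and 10.8% in the second. It held up to 46.1% elsewhere, though 8.45% in adult exposed 3. RNA of other organisms stays open: crickets, springtails and mites together were above the median library in 2 of the 4 libraries (4.717% and 4.018% in the second pair, 0.129% and 0.083% in the first), and a spider best hit does not show that the RNA came from the spider. A mislabelled library stays open: the egg yolk list held 0.105% of spider counts in adult control 1, within the 0.105% to 0.441% of offspring and below the 0.16% to 2.756% of the other adults, which may also reflect a female that was not producing yolk. The lowest offspring value is that of offspring of control 3, its closest library, and the next is 0.18% in offspring of control 2. Lying within the offspring range therefore restates the pairing, and cannot show which library, if any, was mislabelled. No biological explanation was tested for this pattern.

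The 10 calls in offspring were mostly carried by 1 library, with over 90% of the CPM of the offspring of exposed in 1 library for 9 of them, which restates the pattern and does not test its cause. That maternal exposure changed all 10 genes in every animal sampled stays open: the groups overlapped in 3 of the 10, short of the 5 set against it, and an exposed library below a control does not show an animal left unchanged. RNA of other organisms also stays open: over 14110 clusters with a spider best hit 0 were called, the outcome set beforehand for that explanation. It was not taken to settle the matter because 5 of the 10 have a spider best hit themselves, fewer clusters were tested, and a best hit names the nearest database entry and not the source. Differences between mothers or between animals were not tested.

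Among adults 338 clusters were at 0 in all 3 libraries of 1 group and at 10 or more counts in each of the other 3, 249 of them at 0 in the exposed and 89 in the controls. With the 6 libraries thinned to the lowest total 105 of the 338 still met this rule (97 to 108 over 10 draws). In the first draw 45 clusters in all met it at 0 in the exposed and 83 at 0 in the controls. Every control library was deeper than every exposed one, so lower depth could not give zeros in the controls. Thinning did not test depth there. Depth alone is argued against only for clusters still at 0 in the exposed, at most 45 in that draw. For the rest of the 249 it stays open. The larger number at 0 in the exposed was not kept at equal depth. After thinning 64.8% (95% Clopper-Pearson interval 55.9% to 73.1%) of such clusters were at 0 in the controls, against 26.3% (21.7% to 31.4%) before, as depth would give. Reads shared between near-identical clusters stay open. For 115 clusters, others of the same assembly group and product moved the opposite way in 51.3% (41.8% to 60.7%), below the 75% set beforehand. In the 37 with a level at least the mean of the others this was 51.4% (34.4% to 68.1%). An assembly group can be very large, and its clusters of 1 product name need not be near-identical or share reads. This test therefore cannot argue against sharing. For 223 without expressed others the comparison could not be made. An effect of exposure on these clusters was not tested apart from these.

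Other splits of the 6 libraries into 3 against 3 number 10 with the real one, too few for a share under 0.05. For adults the real count of calls is 0, which all 10 splits reach by necessity (highest other 3), so that count says nothing on chance. In adults 8 had at least as many lists as the real 6 (highest other 11) and 6 at least as many clusters at 0 in 1 whole group as the real 338 (highest other 494). For offspring these were 7 for 10 calls (highest other 31), 6 for 10 lists (highest other 16) and 8 for 246 clusters at 0 (highest other 4131). For stage they were 6 for 11 calls (highest other 10336) and 3 for 17 lists (highest other 18). The split with 10336 calls set adult control 1, offspring of control 2 and offspring of control 3 against the other 3 controls, and that with 4131 set offspring of exposed 2, offspring of control 2 and offspring of control 3 against the other 3 offspring libraries. Both go with the structure of the samples seen among the closest libraries. They also put the deepest libraries of the comparison on the same side. Neither was repeated on thinned counts, so depth was not told apart from that structure.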

How the results depend on the processing

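The fits on spider best hits, with depth class as a covariate, with clusters of 1 product summed and without the 2 deepest offspring libraries were chosen after seeing the data. Counts are numbers of calls for adults, offspring, the difference of effects and stage, and the cause was not tested except where fewer clusters or libraries entered.

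With RLE scaling adults had 1 call and offspring 2. DESeq2 gave 391, 3553, 1660 and 1556 calls, of which 0, 1, 19 and 1 were shared with edgeR's. Limma voom gave 0 in offspring, 3 for the difference and 15402 for stage. Without a filter the counts were 259, 0, 6 and 0, and with at least 50 counts in 3 libraries 0 in offspring, for the difference and for stage. All 12 libraries in 1 fit gave 143 calls in adults, 55 in offspring and 125 for stage. Named products alone gave 0 for the difference and 3 for stage, and without clusters annotated to other organisms offspring had 0. Spider best hits alone gave 0 calls in offspring, for the difference and for stage, and 10 lists for stage. Products summed gave 0, 37 and 0 for the same 3. Depth class as a covariate gave 45 for the difference and 19 for stage, and offspring without the 2 deepest libraries had 23, of which 9 were shared.

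The numbers of the libraries do not pair them: the correlation of libraries with 1 number, after removal of group means, was −0.036, −0.048 and 0.004 in adults, −0.002, 0.39 and −0.441 in offspring and −0.691, −0.09 and −0.496 for stage. A replicate block gave 14, 0, 10 and 0 calls, and 7, 8 and 15 lists for adults, offspring and stage. In offspring the calls of the receptors (0.218) and of haemocyanin (0.996) were lost with it, and for stage those of egg yolk (0.0841), immune defence (0.0841) and silk (0.274).

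Leaving out 1 library gave 0 to 522 calls in adults, 0 to 11 in offspring, 3 to 85 for the difference and 1 to 89 for stage. The numbers of lists were 5 to 9 in adults, 6 to 15 in offspring and 4 to 15 for stage, and the correlation of effects was −0.051 to 0.254, against 0.177 to 0.207 in the other settings. With an estimated correlation, and with fry, 0 lists were called in adults, offspring and stage. With 1 entry per product 5 of 25 lists were called in offspring and 10 of 24 for stage, where haemocyanin in both and silk for stage were not tested.

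Named clusters were followed under RLE scaling, DESeq2, a replicate block and each library left out, and not under the other settings. They kept their direction and side of the threshold in all of those where they were tested for 6 of 22 in adults, 14 of 22 in offspring, 0 of 10 for the difference and 3 of 10 for stage. The log2 difference of laminin subunit alpha-2 (Cluster-217197.16698) reversed to −1.46 without offspring of control 3. Depth limits what can be seen, since 3 counts are 0.878 CPM in the shallowest library and 0.103 CPM in the deepest.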

Other observations

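The comparisons of list shares were chosen after the results were seen. As shares of spider counts, heat shock proteins held 0.852% ± 0.057 in adult exposed and 0.689% ± 0.066 in adult control libraries (SD, n = 3), and the proteasome 0.376% ± 0.065 and 0.271% ± 0.025. In offspring of exposed and of control the proteasome held 0.503% ± 0.225 and 0.244% ± 0.06, and iron and haem handling 1.314% ± 0.332 and 0.79% ± 0.085. Of the single clusters, 71 of 98 for heat shock (median log2 fold change −0.58) and 38 of 61 for the proteasome (−0.28) were lower in exposed adults, beside a median of −0.62 over all clusters. In each of these 4 shares the groups did not overlap, which gives a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. That held for 2 of the 26 lists (7.7%) in adults and 2 in offspring, where chance gives 10%, and the smallest p adjusted by Benjamini-Hochberg was 0.867 and 0.743.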
